A study of Mus musculus with 12 samples.

How the data were processed

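The data are RNA-seq counts from the cochlea of FVB/NCrl mice at postnatal day 60, 12 libraries in 3 groups of 4, after 30 minutes at 70 (ambient), 94 or 105 dB SPL. Per the labels' protocols, RNA was harvested with TRIzol right after the exposure, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The values are whole-number read counts per gene, not normalised, in 1 deposited table of 35496 Ensembl genes, and the authors' steps are known only in part. Per the submitters' processing notes, the tools were CASAVA, STAR and featureCounts 1.5.0-p3, and the build was mm10. Their parameters, the gene annotation, the treatment of reads with several alignments and the use of strand are not given in the sources used here. For this reason genes with near-identical copies and genes that overlap another gene are given as uncertain.

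Groups and replicate numbers came from the sample titles, and each column of the table was matched to a sample by its name. In the 105 dB group the codes in the titles skip a number, so that code 4 is replicate 3 and code 5 is replicate 4; replicate numbers are used here. No column with values was left unused. Of the 35496 genes, 35449 had a symbol in the GENCODE M21 annotation of GRCm38, the assembly named mm10 elsewhere, and genes without one held 0.0269% of counts. Gene positions, GC content and exon length are from that annotation and assembly. No pair of libraries was a duplicate: within groups, Pearson's r of log2 CPM was 0.984 to 0.991, and chi-square per degree of freedom over genes was 13.2 to 57.4.

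Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 19497 genes and 99.9% of counts. Library sizes were scaled with TMM factors. A negative binomial model with a mean per group was fitted to all 12 libraries (9 residual degrees of freedom, common biological coefficient of variation 0.133) by glmQLFit with robust dispersions, and each contrast was tested with glmQLFTest. P-values were adjusted by Benjamini-Hochberg over the 19497 genes, with 0.05 as the threshold and no fold threshold. CPM (counts-per-million) values are TMM-scaled, and log2 fold changes are those of the fit, with a standard error derived from the F statistic. Depth sets a floor of 3 counts, which is 0.0709 to 0.0963 CPM per library; such limits cover counting error only.

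The design, the lists and the rule for named genes were fixed before the data were examined. In each comparison the rule took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with an average log2 CPM of at least 1, no overlap between the groups' libraries and a symbol that is not a clone or predicted-model name. It also took 4 members of each pathway list with the smallest p at 105 dB, the 3 most abundant members of each cell type list that passed in any comparison, and Fos, Hspa1a, Hspa1b and Hspa5. This gave 126 distinct genes, of which the text prints those that matter most; a few are not reported here, and they stay in all counts and list tests.

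There were 15 pathway lists (immediate early genes, heat shock response, endoplasmic reticulum stress and unfolded protein response, proteasome subunits, chaperonin and prefoldin, autophagy and lysosome, NRF2 response, NF-kB and cytokine response, glucocorticoid response, hypoxia and glycolysis, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, synapse and neuronal activity, extracellular matrix). The 17 cell type lists covered hair cells, supporting cells, spiral ganglion neurons, Schwann cells, central glia, stria vascularis, fibrocytes, bone cells, erythroid cells, neutrophils, B cells, macrophages, endothelial cells, skeletal muscle, cartilage, proliferating cells and adipocytes. Together they held 659 distinct genes. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 32 lists of a contrast. At this preset 12, 16 and 4 lists passed in the 94 to 70 dB, 105 to 70 dB and 105 to 94 dB contrasts. With the correlation estimated from the data 1, 2 and 0 passed, namely immediate early genes at 94 dB and immediate early and glucocorticoid genes at 105 dB. By fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 11, 4 and 1 passed. The signs of a list's median, mean and camera direction differed in 8, 5 and 10 lists, none of which passed.

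The alternatives were DESeq2's size factors and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 4 libraries, a fit of the 8 libraries compared, a replicate block, a block by the number in the sample code, 1 surrogate variable (sva 3.50.0), no genes over 1% of a library, a fold threshold of 1.2, DESeq2 1.42.0, and each library left out. Added after the data were seen were a smooth trend on GC content and exon length fitted per library with mgcv 1.9.3 and removed, the fit without 94 dB replicates 3 and 4, the fit without 70 dB replicate 4 (also among the libraries left out), and that trend together with the block. For the overlap of both levels with their common controls, 20 simulations of unchanged groups were drawn and the controls were split 2 and 2 in 6 ways. Other splits of the libraries were counted over all 35 splits of each contrast and over 100 regroupings of the 12 libraries.

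The code was tested on simulated counts for 19497 genes drawn from the libraries' means and sizes, with 50 genes changed at each of 4 folds. For 94 against 70 dB it recovered 14% of genes changed 1.3-fold, 64% at 1.5-fold, 86% at 2-fold and 98% at 3-fold, with 9 false among 140 calls (6.43%). For 105 against 70 dB it recovered 26%, 72%, 82% and 96% in the same order, with 11 false among 149 calls (7.38%). Where a GC trend was added to the simulated 94 dB libraries, calls went from 2368 to 138 on its removal, 129 of them true, and the same test for 105 dB gave 2484 and 143 (135 true). A list raised in the simulation had an adjusted p of 1.06e-24 at 94 dB and 5.47e-18 at 105 dB, with 0 of the other lists called. Genes were drawn independently there, so this does not test list calls that arise from correlation between genes.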

Results

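RNA was sequenced from the cochlea, the hearing organ of the inner ear, of mice of the inbred FVB/NCrl strain at postnatal day 60. Awake animals spent 30 minutes in noise of 70, 94 or 105 dB SPL (sound pressure level on a decibel scale), and RNA was taken immediately afterwards. The 70 dB group was held at ambient sound and is the control. Each group had 4 libraries, 12 in all. Total counts per library ran from 31141706 to 42317781 at 70 dB, 32302796 to 38733490 at 94 dB and 32057388 to 40239711 at 105 dB. The study's title concerns hearing loss, protein misfolding stress and the proteostasis network, the chaperones and degradation systems that handle misfolded protein. The labels do not say whether a library came from 1 animal or a pool, so p-values measure the spread between these samples, which may be technical.

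The libraries of the 3 groups differed in makeup. Genes encoded by the mitochondrial genome took 5.36 ± 0.25% of counts at 70 dB, 3.13 ± 0.49% at 94 dB and 4.77 ± 0.43% at 105 dB (SD, n = 4). By a two-sided exact permutation test the 94 dB share differed from 70 dB with p = 0.0286, the smallest that 70 assignments can give, and an adjusted p of 0.0571 over 6 tests. Haemoglobin genes took 1.84 ± 0.17% at 70 dB, 2.42 ± 0.60% at 94 dB and 2.40 ± 0.35% at 105 dB (SD, n = 4). For haemoglobin the exact permutation p was 0.114 at 94 dB (adjusted 0.137) and 0.0286 at 105 dB (adjusted 0.0571). Replicates 3 and 4 at 94 dB stood apart from the other 94 dB libraries, with mitochondrial shares of 2.68% and 2.73% against 3.53% and 3.59%. Their haemoglobin shares were 2.90% and 2.95% against 1.75% and 2.07%. Replicate 4 at 70 dB lay farthest out on the first principal component, which held 24.5% of the variance.

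**Figure D1:**
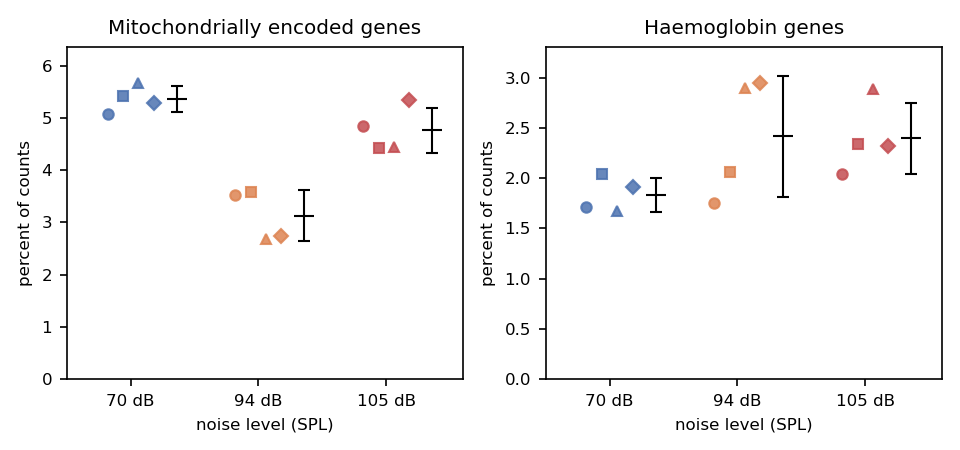
Percent of all counts taken by mitochondrially encoded genes (left) and haemoglobin genes (right) in each library, against the noise level in dB SPL. Symbols mark replicates 1 (circle), 2 (square), 3 (triangle) and 4 (diamond), and the black bar with caps is the mean ± SD (n = 4); the mitochondrial share averaged 5.36% at 70 dB and 3.13% at 94 dB.

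The first comparison asked what 94 dB noise did to cochlear transcripts against ambient sound. Immediate early genes, which are transcribed within minutes of a stimulus, and glucocorticoid targets rose as lists, while mitochondrially encoded genes fell. The last 2 list calls ended with an estimated correlation (adjusted p = 0.0608 and 0.116 with an estimated correlation). Among the genes named by the rule fixed beforehand, the largest rise was of Ddit4 (ENSMUSG00000020108; mm10 chromosome 10, 59949669 to 59951834), a stress-induced inhibitor of mTOR signalling, from 26.3 ± 1.66 CPM at 70 dB to 288 ± 68.8 at 94 dB (SD, n = 4). Nfkbia, which encodes an inhibitor of NF-kB, rose from 57.8 ± 4.96 to 125 ± 10.5 CPM (SD, n = 4). Snai2, a transcriptional repressor, fell from 12.4 ± 0.807 to 5.57 ± 0.879 CPM (SD, n = 4). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5085 of 19497 genes passed an adjusted p of 0.05, 2716 higher and 2369 lower. With upper-quartile factors the balance turned, to 2329 higher and 2847 lower. Without 94 dB replicates 3 and 4, a choice made after the data were seen, 1610 passed. Of the 5085, 244 were over 2-fold higher and 91 over 2-fold lower. Every 94 dB library lay on 1 side of every 70 dB library in 4945 genes (25.4%), where chance gives 2.86%.

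Among the 10 strongest risers named by the rule fixed beforehand were members of the AP-1, CREB and nuclear receptor families. The transcription factor Fos (ENSMUSG00000021250; mm10 chromosome 12, 85473890 to 85477273) rose from 12.5 ± 3.72 to 51.9 ± 5.29 CPM (SD, n = 4), a log2 fold change of 2.05 (SE 0.22; adjusted p = 2.05e-04). The orphan nuclear receptor Nr4a1 (ENSMUSG00000023034; mm10 chromosome 15, 101254269 to 101274795) rose from 36.0 ± 13.3 to 164 ± 19.4 CPM (SD, n = 4), with a log2 fold change of 2.19 (adjusted p = 1.09e-04). Atf3, Apold1 and the clock gene Per1 rose with log2 fold changes of 2.31, 2.10 and 2.15. Cebpb rose by 2.61 on the log2 scale, but it overlaps Tmem189 on the other strand, and the counts here cannot tell the strands apart if none was used. Also in this set were Atp5k, a small ATP synthase subunit, at 2.54, the haemoglobin gene Hbb-bt at 2.30, and Pcp4 at 1.94. Hbb-bt is nearly identical to Hbb-bs, and Pcp4 overlaps Igsf5, so both values are uncertain. All 10 kept their calls without each library in turn, and Atp5k lost its own without 94 dB replicates 3 and 4 together (0.0535, in a range of 3.40e-07 to 0.0535).

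Genes of the opposite direction were less stable. Of the 10 named, mt-Nd6, Plagl1, Snai2, mt-Nd5 and St8sia3 kept their calls without each library, and Necab1, Scn9a, Chl1, Tmem233 and Luzp2 did not. Snai2 (ENSMUSG00000022676; mm10 chromosome 16, 14705852 to 14709385) had a log2 fold change of -1.16 (SE 0.12; adjusted p = 2.01e-05 by edgeR's quasi-likelihood test). Plagl1, an imprinted zinc finger gene, fell from 20.4 ± 2.84 to 8.82 ± 2.09 CPM (SD, n = 4). St8sia3, a sialyltransferase gene, fell from 11.1 ± 4.73 to 5.29 ± 0.392 CPM (SD, n = 4), a call lost without 94 dB replicates 3 and 4 together (0.0521, in a range of 1.83e-05 to 0.0521). Necab1 read 10.1 ± 9.90 CPM at 70 dB, of which replicate 4 held 24.9, against 2.68 ± 0.699 at 94 dB (SD, n = 4). The adjusted p of the 5 less stable genes lay between 0.0259 and 0.0435. Without 94 dB replicate 3 they were 0.0672 for Necab1, 0.0948 for Scn9a, 0.103 for Chl1, 0.0631 for Tmem233 and 0.0674 for Luzp2, and 94 dB replicate 2 ended the same calls (up to 0.0969 for Chl1). Leaving out 94 dB replicate 4 ended all but that of Luzp2 (up to 0.101 for Chl1), and Scn9a or Chl1 also lost theirs without 94 dB replicate 1, 70 dB replicates 3 or 4 or any 105 dB library (0.0515 to 0.0768). Over all alternatives these p ran from 0.00240 for Luzp2 to 0.250 for Chl1.

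Among the pathway lists fixed beforehand, immediate early genes had the highest median. Of 45 tested, 33 rose and 2 fell, and 34 rose and 2 fell when adjusted over the list alone. Their median log2 fold change was 0.74, and camera gave an adjusted p of 9.77e-43 (adjusted p = 0.0127 with an estimated correlation). Sik1, Dusp1 and Gadd45g, a kinase, a phosphatase and a growth arrest gene, rose by 1.51, 1.70 and 1.58 on the log2 scale. In the glucocorticoid list, 12 of 20 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.60 and a camera adjusted p of 1.79e-18 (adjusted p = 0.0608 with an estimated correlation). Sgk1 and Errfi1 rose by 1.07 and 1.07, while Zbtb16, named after its value was seen, fell with a log2 fold change of -0.81. Per1 and Errfi1 stand in both lists. The NF-kB and cytokine list had 7 of 27 members higher and 1 lower (8 and 1 adjusted over the list alone), with Nfkbia at 1.11, Relb at 0.57 and Vcam1 at 0.51 (camera adjusted p = 0.00455; adjusted p = 0.516 with an estimated correlation).

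Of 31 heat shock genes, 6 rose and 2 fell, with the same counts adjusted over the list alone. Over all genes tested 26.1% were called at 94 dB, a share near that of this list. The cochaperone gene Dnajb1 (ENSMUSG00000005483; mm10 chromosome 8, 83608193 to 83612653) went from 90.5 ± 27.2 to 133 ± 14.2 CPM (SD, n = 4), a log2 fold change of 0.55 with an adjusted p of 0.0449 by edgeR's quasi-likelihood test. Its call was lost without 10 of the 12 libraries, all but 70 dB replicate 3 and 105 dB replicate 3, with 0.106 without 70 dB replicate 4 and 0.101 without 94 dB replicate 1, in a range of 0.00398 to 0.189. Dedd2, a death effector domain gene in the same list, rose by 0.58, and the polyubiquitin gene Ubb, named after its value was seen, by 0.51. The inducible HSP70 gene Hspa1a (ENSMUSG00000091971; mm10 chromosome 17, 34969190 to 34972156) read 11.1 ± 10.6 CPM at 70 dB and 26.5 ± 4.51 at 94 dB (SD, n = 4), and did not pass (adjusted p = 0.158). The 70 dB libraries spread widely there, from 2.90 CPM in replicate 1 to 25.4 in replicate 3, and without 70 dB replicate 3 the adjusted p was 0.0245, the lowest of its alternatives, which reached 0.381. Its near-identical neighbour Hspa1b read 52.1 ± 49.0 and 76.9 ± 14.0 CPM (SD, n = 4; adjusted p = 0.544), and counts of this pair are uncertain because reads may be shared. As a list, heat shock genes had a median of 0.19 and a camera adjusted p of 0.0412 (adjusted p = 0.810 with an estimated correlation). That call was lost without 70 dB replicates 1 (0.306) or 4 (0.192) and 94 dB replicates 1 (0.110) or 2 (0.0786), and over all its alternatives the adjusted p ran from 1.34e-05, without 70 dB replicate 3, to 0.810.

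The endoplasmic reticulum stress list had 9 of 31 members higher and 1 lower, where 26.1% of all genes tested were called in either direction. The translational stress factor Atf4 (ENSMUSG00000042406; mm10 chromosome 15, 80255184 to 80257541) rose from 168 ± 14.8 to 254 ± 7.85 CPM (SD, n = 4; edgeR adjusted p = 2.15e-04). Sdf2l1, Derl3, Creld2 and Hyou1, chaperone and degradation genes named after their values were seen, rose by 0.80, 0.56, 0.50 and 0.45. Hspa5, the main chaperone of this compartment, read 842 ± 216 and 964 ± 77.5 CPM (SD, n = 4) and did not pass (adjusted p = 0.304; 0.0174 without 70 dB replicate 3, in a range of 0.0174 to 0.625). Camera gave the list an adjusted p of 0.0513, which fell below 0.05 without 70 dB replicate 2 (0.0402) or 3 (6.90e-05), 94 dB replicate 1 (0.0412) or 3 (0.0340) and 105 dB replicate 2 (0.0474), in a range of 6.90e-05 to 0.810. Of 31 proteasome subunits 8 rose and 3 fell (10 and 3 adjusted over the list alone), with Psma6 at 0.28 and Psmb5, named after its value was seen, at 0.96. The median over this list was only 0.088, and 20 members were not called. The camera adjusted p was 0.0415 (adjusted p = 0.810 with an estimated correlation), and it passed 0.05 without 70 dB replicate 1 (0.213) or 3 (0.0568) and 94 dB replicate 4 (0.0892), in a range of 0.00255 to 0.810. Chaperonin and prefoldin genes had 5 of 14 higher and 1 lower, with Cct7 at 0.27 (camera adjusted p = 0.0153; adjusted p = 0.587 with an estimated correlation). Cct7 lost its own call without 94 dB replicates 3 and 4 together (0.0665, in a range of 6.55e-04 to 0.0665). Psma6 lost its own call without 70 dB replicates 1 (0.0716) or 3 (0.0531) and 94 dB replicates 3 (0.0616) or 4 (0.0837), in a range of 0.0129 to 0.228.

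Of the 13 mitochondrially encoded genes 10 fell and none rose, with a median log2 fold change of -0.81 and a camera adjusted p of 5.24e-12 (adjusted p = 0.116 with an estimated correlation). The complex I gene mt-Nd2 fell from 5296 ± 749 to 2749 ± 352 CPM, and the cytochrome oxidase gene mt-Co1 from 19753 ± 1178 to 12109 ± 1648 CPM (SD, n = 4). mt-Nd5 and mt-Nd6, at -1.09 and -1.21, overlap on opposite strands. Nuclear genes of oxidative phosphorylation had 22 of 38 higher and none lower (27 higher adjusted over the list alone), with Ndufa1 at 1.22 and Sdhd at 0.56 (median 0.39; camera adjusted p = 1.57e-12; adjusted p = 0.516 with an estimated correlation). Cytosolic ribosomal protein genes had 24 of 45 higher and none lower (33 higher adjusted over the list alone), with Rps19 at 0.95 and Rps20 at 0.55 (median 0.48; camera adjusted p = 1.50e-12; adjusted p = 0.587 with an estimated correlation). Ribosomal genes have many processed copies, so their values are uncertain. Fold changes at 94 dB followed GC content and transcript length over 15010 genes, with Spearman's rho of 0.523 and -0.352 across genes, which are not independent replicates. With that trend removed, a check added after the data were seen, 3203 genes passed and the 3 medians were -0.74, 0.21 and 0.33.

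The counts of this paragraph stand beside 26.1% of all genes tested called at 94 dB in either direction. Synapse genes had 7 of 24 lower and none higher (8 lower and 1 higher adjusted over the list alone), with the glutamate receptor gene Gria2 at -0.41, and Snap25, which also stands in the spiral ganglion list, at -0.38 (camera adjusted p = 0.0257; adjusted p = 0.709 with an estimated correlation). That list call was lost without 70 dB replicate 4 (0.0937) or 94 dB replicate 2 (0.0630), in a range of 0.00255 to 0.709, and with the GC and length trend removed Gria2 and Snap25 had adjusted p of 0.717 and 0.240, in ranges of 9.10e-04 to 0.735 and 7.51e-05 to 0.240. Schwann cell and myelin genes had 5 of 16 lower and 1 higher, with Pmp22 from 682 ± 165 to 399 ± 51.9 CPM (SD, n = 4), and a camera adjusted p of 0.0421 (adjusted p = 0.810 with an estimated correlation). Pmp22 had 0.0990 without 94 dB replicates 3 and 4 together, in a range of 1.59e-05 to 0.0990. For the list, without 70 dB replicate 1 it was 0.306, without 70 dB replicate 3 it was 0.150, without 94 dB replicate 2 it was 0.234 and without 105 dB replicate 3 it was 0.0589, in a range of 2.63e-05 to 0.810. Neutrophil genes had 5 of 16 higher, with S100a9 at 2046 ± 224 and 2981 ± 852 CPM (SD, n = 4; list adjusted p by camera = 0.0274; adjusted p = 0.810 with an estimated correlation). The neutrophil call was lost without 70 dB replicates 1 (0.184) or 4 (0.0584) and 94 dB replicates 2 (0.179) or 4 (0.0951), in a range of 2.80e-05 to 0.810. S100a9 lost its own call without 70 dB replicates 1 (0.0883), 3 (0.0849) or 4 (0.0634) and 94 dB replicates 2 (0.0567), 3 (0.0872) or 4 (0.0957), in a range of 7.94e-04 to 0.367. Hair cell genes had 1 of 20 higher and 0 lower (adjusted p = 0.890), and supporting cell genes 4 of 19 higher and 5 lower (adjusted p = 0.975).

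**Figure D2:**
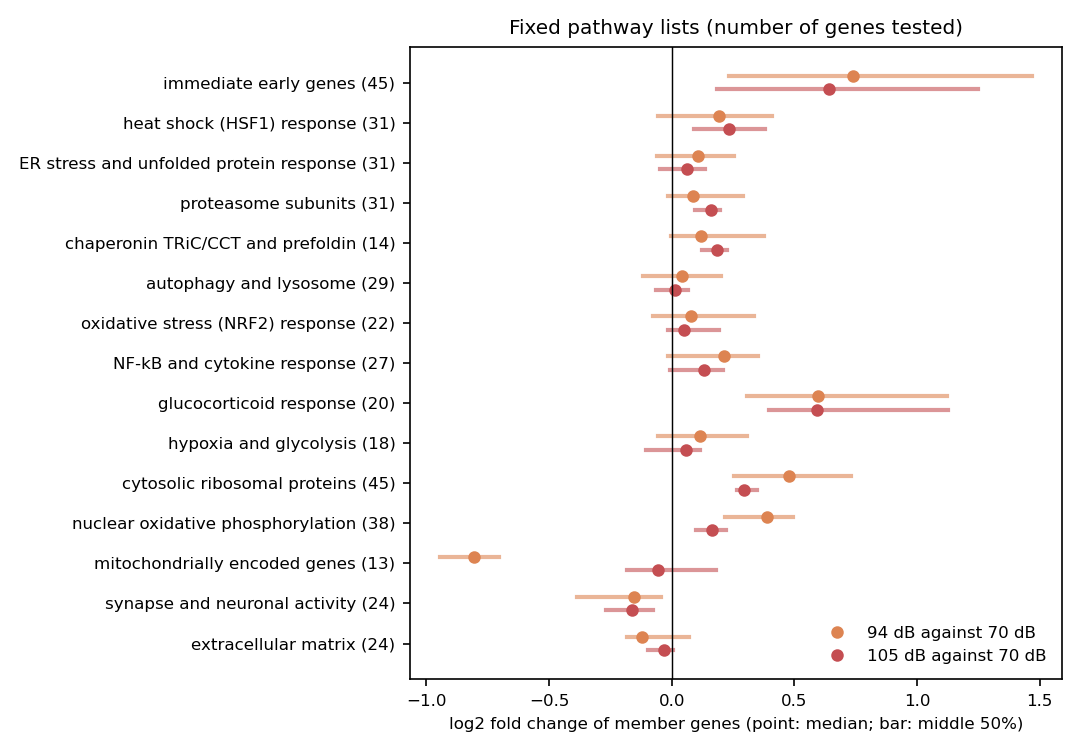
Log2 fold change of the member genes of each of the 15 fixed pathway lists at 94 dB (orange) and 105 dB (red) against 70 dB; points are medians over members, bars the middle 50% of members, and the number of genes tested is in brackets. Immediate early genes had medians of 0.74 and 0.64, and mitochondrially encoded genes a median of -0.81 at 94 dB.

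The second comparison set the loudest noise, 105 dB, against ambient sound. Immediate early and glucocorticoid genes rose here as well, and far fewer other genes passed. Fosb (ENSMUSG00000003545; mm10 chromosome 7, 19302696 to 19310051), a partner of JUN proteins, rose from 1.25 ± 0.471 to 7.77 ± 0.850 CPM (SD, n = 4), a log2 fold change of 2.62 (SE 0.20; adjusted p = 1.06e-06). Fos rose from 12.5 ± 3.72 to 80.6 ± 18.8 CPM and Ddit4 from 26.3 ± 1.66 to 167 ± 16.3 CPM (SD, n = 4). Nfkbia (ENSMUSG00000021025; mm10 chromosome 12, 55489410 to 55492647) rose from 57.8 ± 4.96 to 130 ± 2.94 CPM (SD, n = 4; adjusted p = 2.05e-07). In all, 316 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 217 higher and 99 lower. Thus 68.7% of the calls were higher, against 58.3% with upper-quartile factors. Only 41 were over 2-fold higher and 6 over 2-fold lower, and the 2 groups did not overlap in 2107 genes (10.8%), where chance gives 2.86%. The count depended on single libraries and on the settings. It was 126 without 105 dB replicate 2, 187 without 105 dB replicate 3, 149 without 70 dB replicate 4 and 191 without 70 dB replicate 1, while 1 surrogate variable left 101, and DESeq2 gave 887, no low-count filter 523, a replicate block 479 and that block with the GC and length trend removed 652.

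Of the 10 strongest risers 9 are reported here, and all 9 kept their calls without each library. Besides Fos, Ddit4 and Fosb they were Nr4a1, Apold1, Atf3, Cebpb, Nr4a3 and Per1. Nr4a1 and Nr4a3, orphan nuclear receptors, rose by 2.43 and 2.07 on the log2 scale, and the endothelial immediate early gene Apold1 by 2.18. Atf3 rose by 2.11, Per1 by 1.90 and Cebpb, which overlaps Tmem189, by 2.07. Of the 9 reported among the 10 strongest fallers, Snai2, Cx3cr1 and Pou3f2 kept their calls. The fractalkine receptor gene Cx3cr1 (ENSMUSG00000052336; mm10 chromosome 9, 119901616 to 120069879), a marker of microglia and macrophages, fell from 23.7 ± 2.85 to 13.4 ± 1.52 CPM (SD, n = 4; adjusted p = 4.29e-04). The transcription factor gene Pou3f2 fell from 13.9 ± 0.752 to 8.32 ± 0.695 CPM and Snai2 from 12.4 ± 0.807 to 6.79 ± 0.758 CPM (SD, n = 4). Ccdc170, Folh1, Fzd10, Gpr34, Pla2g3 and Tvp23a, with log2 fold changes from -0.84 to -0.75, each lost the call without 105 dB replicate 3, where their adjusted p were 0.108, 0.0868, 0.0503, 0.0756, 0.0972 and 0.107. Some of these calls also ended without 105 dB replicates 1 (up to 0.109), 2 (0.154) or 4 (0.0638), 70 dB replicates 1 (0.112), 2 (0.0614), 3 (0.0701) or 4 (0.130) and 94 dB replicates 1 (0.0546) or 4 (0.0585), in ranges from 2.19e-04 for Fzd10 to 0.347 for Tvp23a.

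**Figure D3:**
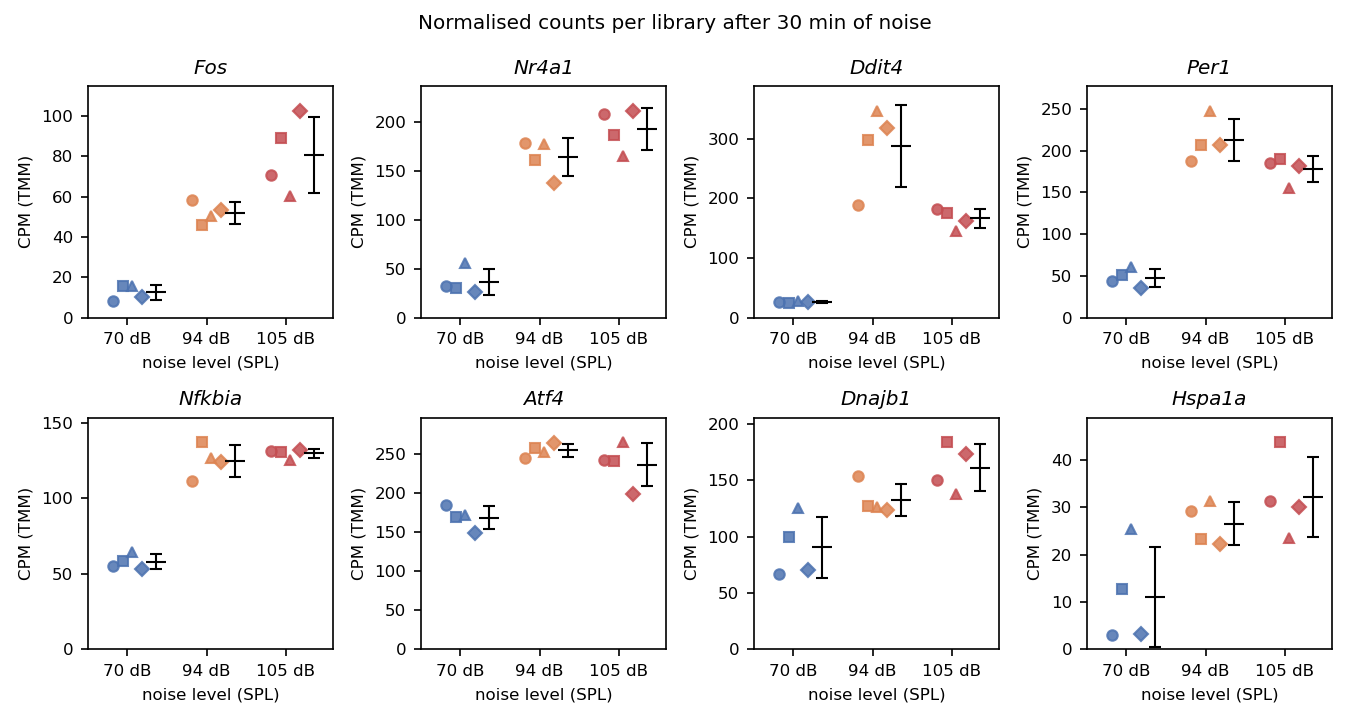
CPM (TMM-scaled) of 8 genes in each library against the noise level in dB SPL; symbols mark replicates 1 (circle), 2 (square), 3 (triangle) and 4 (diamond), and the black bar with caps is the mean ± SD (n = 4). Fos averaged 12.5 CPM at 70 dB, 51.9 at 94 dB and 80.6 at 105 dB, while the 70 dB libraries of Hspa1a spread from 2.90 to 25.4 CPM.

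Of 45 immediate early genes 25 rose and none fell (34 and 1 adjusted over the list alone), with a median log2 fold change of 0.64 and a camera adjusted p of 1.48e-92 (adjusted p = 6.81e-04 with an estimated correlation). Sik1, Dusp1 and Gadd45g rose by 1.54, 1.82 and 1.58. Glucocorticoid targets had 9 of 20 higher and none lower (17 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 3.13e-42; adjusted p = 0.00362 with an estimated correlation). Sgk1 rose from 114 ± 16.0 to 241 ± 29.1 CPM and Errfi1 from 95.3 ± 13.6 to 223 ± 33.5 CPM (SD, n = 4). In the NF-kB and cytokine list 2 of 27 genes rose, Nfkbia at 1.16 and the adhesion molecule Vcam1 at 0.44 (camera adjusted p = 0.0142; adjusted p = 0.443 with an estimated correlation). The list call was lost without 70 dB replicate 4 (0.124) and with 1 surrogate variable (0.377), in a range of 0.00182 to 0.443. Vcam1, at an adjusted p of 0.0421, lost its call without 70 dB replicates 1 (0.111) or 4 (0.127), 94 dB replicate 4 (0.0573) and 105 dB replicates 1 (0.0752), 2 (0.157), 3 (0.0946) or 4 (0.0520), in a range of 0.00410 to 0.347.

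Heat shock genes had 2 of 31 higher (3 adjusted over the list alone), a median of 0.23 and a camera adjusted p of 1.28e-06 (adjusted p = 0.443 with an estimated correlation; fry gave 0.101). The 2 called were Dnajb1, from 90.5 ± 27.2 to 161 ± 21.1 CPM, and Dedd2, from 44.7 ± 2.95 to 58.5 ± 2.92 CPM (SD, n = 4). By edgeR's quasi-likelihood test Dnajb1 had an adjusted p of 0.0477, lost without each library except 70 dB replicate 3 (0.154 without 105 dB replicate 2, 0.129 without 70 dB replicate 4), in a range of 4.27e-05 to 0.321. Dedd2 had 0.0116, and 0.0595 without 105 dB replicate 2, in a range of 2.98e-04 to 0.146. Hspa1a read 32.2 ± 8.44 CPM, Hspa1b 91.8 ± 18.5 CPM and Hspa5 887 ± 7.06 CPM at 105 dB (SD, n = 4), and none of them passed (adjusted p = 0.218, 0.507 and 0.796). The cochaperone genes Dnajb4 and Bag3 had log2 fold changes of 0.43 and 0.26 (adjusted p = 0.0849 and 0.165), which passed only without 70 dB replicate 3 among the libraries left out (0.0158 and 0.0436, in ranges of 0.0158 to 0.431 and 0.0436 to 0.575). None of 31 proteasome genes passed, while their median was 0.16, beside 0.088 at 94 dB. Camera gave that list an adjusted p of 1.45e-05 at 105 dB (adjusted p = 0.443 with an estimated correlation). Since the adjusted threshold is less strict where more genes change, counts of called members do not rank the levels. The chaperonin list likewise had no member past the threshold over all genes and 4 higher adjusted over the list alone, with Cct5 at 0.28 and Cct8 at 0.27, which passed with DESeq2 (0.00545 and 0.0448, in ranges of 0.00545 to 0.329 and 0.0375 to 0.409; camera adjusted p = 1.96e-04; adjusted p = 0.417 with an estimated correlation). Atf4 rose from 168 ± 14.8 to 236 ± 27.9 CPM (SD, n = 4; adjusted p = 0.00489), the 1 call among 31 endoplasmic reticulum stress genes. Atf4 lost that call with 1 surrogate variable (0.0713), in a range of 8.97e-06 to 0.0713. The list had a camera adjusted p of 0.138, and 2.68e-04 without 70 dB replicate 3, in a range of 2.68e-04 to 0.984.

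Cytosolic ribosomal protein genes had 2 of 45 higher at 105 dB (27 adjusted over the list alone), a median of 0.30 and a camera adjusted p of 1.49e-14 (adjusted p = 0.433 with an estimated correlation). The 2 called, Rps19 and Rps20, both lost their calls without 70 dB replicates 1, 3 or 4 and 105 dB replicates 1, 2 or 3 (up to 0.141 and 0.142) and with the GC and length trend removed (0.0581 and 0.0622). Rps20 lost it without 94 dB replicate 3 as well (0.0515), and their ranges were 0.00118 to 0.266 and 0.00373 to 0.253. Nuclear genes of oxidative phosphorylation had 1 of 38 higher (7 adjusted over the list alone; camera adjusted p = 2.70e-06; adjusted p = 0.477 with an estimated correlation). That 1, Ndufa1, had an adjusted p of 0.0445 and lost its call without 70 dB replicates 1 (0.106), 3 (0.0949) or 4 (0.0950), 94 dB replicate 4 (0.0573) and 105 dB replicates 1 (0.0968), 2 (0.177) or 3 (0.114). It also lost it with upper-quartile factors (0.0546), the replicate block (0.0502) and the GC and length trend removed (0.203), in a range of 0.00587 to 0.204. None of the mitochondrially encoded genes passed, and their list had an adjusted p of 0.387. Gpx1, a glutathione peroxidase gene and the 1 call in the NRF2 list, went from 806 ± 68.1 to 1083 ± 87.1 CPM (SD, n = 4; adjusted p = 0.0340). Its call was lost without 70 dB replicates 1 (0.0871), 3 (0.0831) or 4 (0.101) and 105 dB replicates 2 (0.144) or 3 (0.105), in a range of 0.00146 to 0.234. The NRF2 list itself had an adjusted p of 0.0635, and it passed without 94 dB replicate 1 (0.0460) or 105 dB replicates 3 (0.0443) or 4 (0.0496), in a range of 0.00809 to 0.417. That list also passed with fry (0.0333), and by camera with no low-count filter (0.00809) and without 94 dB replicates 3 and 4 together (0.0452).

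Among cell type lists at 105 dB, Schwann cell genes had a median of -0.37 with 1 of 16 called lower (camera adjusted p = 1.91e-05; adjusted p = 0.456 with an estimated correlation), and Mbp, not called, had a log2 fold change of -0.38. Spiral ganglion genes had a median of -0.21 with 1 of 18 lower (adjusted p = 3.04e-04; adjusted p = 0.433 with an estimated correlation), and synapse genes -0.16 with none of 24 called over all genes and 2 lower adjusted over the list alone (adjusted p = 3.04e-04; adjusted p = 0.433 with an estimated correlation). Central glia genes, listed beforehand as markers of brain stem tissue, had a camera adjusted p of 0.0441 with none of 9 called (adjusted p = 0.529 with an estimated correlation). Which cells these transcripts came from was not tested. That list lost its call without 70 dB replicates 1 (0.161) or 3 (0.0874) and 105 dB replicates 3 (0.183) or 4 (0.0784), in a range of 0.00878 to 0.529. Erythroid genes had 2 of 14 higher and a median of 0.25 (adjusted p = 1.91e-05; adjusted p = 0.417 with an estimated correlation), and neutrophil genes 1 of 16 (adjusted p = 0.00282; adjusted p = 0.529 with an estimated correlation). Skeletal muscle and proliferation lists had no member past the threshold over all genes, with medians of 0.28 and 0.26 and 10 proliferation genes higher adjusted over the list alone (adjusted p = 0.00271 and 1.28e-06; adjusted p = 0.603 and 0.417 with an estimated correlation). With 1 surrogate variable the synapse, spiral ganglion, neutrophil and muscle calls were lost (adjusted p = 0.0689, 0.0987, 0.0689 and 0.0701), in ranges of 1.40e-05 to 0.433, 8.15e-06 to 0.433, 1.24e-04 to 0.529 and 9.54e-06 to 0.603. By camera the neutrophil call also ended with the GC and length trend removed (0.0867) and with the replicate block as well (0.0553). The call of central glia also ended with 1 surrogate variable (0.112), the replicate block (0.0619), the trend removed (0.0737) and both of these (0.0980).

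The third comparison tested 105 dB against 94 dB directly. Mitochondrially encoded genes were higher at 105 dB, and nuclear genes of oxidative phosphorylation lower, as lists. Both calls ended with an estimated correlation (adjusted p = 0.243 and 0.969 with an estimated correlation). mt-Nd4 (ENSMUSG00000064363; mm10 chromosome M, 10167 to 11544) read 2400 ± 468 CPM at 94 dB and 4407 ± 334 at 105 dB (SD, n = 4; log2 fold change 0.88, adjusted p = 6.39e-04), and it overlaps mt-Nd4l. Ndufa1 (ENSMUSG00000016427; mm10 chromosome X, 37187588 to 37191163), a complex I subunit gene, read 53.4 ± 3.56 and 29.5 ± 3.57 CPM (SD, n = 4; adjusted p = 1.94e-04), and 70 dB lay at 22.9 ± 1.32. Fosb was higher at 105 dB than at 94 dB, at 0.92, and Ddit4 lower, at -0.79; without 94 dB replicates 3 and 4 their adjusted p were 0.0945 and 0.0865, in ranges of 3.42e-05 to 0.0945 and 2.41e-06 to 0.0865, and Ddit4 had 0.0809 with the replicate block and the GC and length trend removed. By edgeR's quasi-likelihood test 3372 genes passed a Benjamini-Hochberg adjusted p of 0.05, 1572 higher and 1800 lower (1702 and 1667 with upper-quartile factors), and the groups did not overlap in 4148 genes (21.3%), where chance gives 2.86%. The number was 217 without 94 dB replicates 3 and 4, a choice made after the data were seen, and 1650, 1860, 2057 and 1996 without 94 dB replicate 3, 94 dB replicate 4, 105 dB replicate 2 and 105 dB replicate 4. Fold changes followed GC content over 15010 genes with Spearman's rho of -0.540. With the GC and length trend removed 1915 passed, 1391 of them among the 3372, with a replicate block as well 2040, and with a block by the code number 1414.

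Of the 10 genes with the largest rise from 94 to 105 dB, 3 were mt-Nd6, mt-Nd4 and mt-Nd4l, and among the others were Trf, Ddias, Fosb, Plagl1 and St8sia2. Without 94 dB replicates 3 and 4 mt-Nd6 (0.0713), mt-Nd4l (0.0865), Trf (0.0524) and Plagl1 (0.0709) lost their calls, mt-Nd6 also with the replicate block and the trend removed (0.0772), in ranges from 5.20e-10 for Trf to 0.0865 for mt-Nd4l. The sialyltransferase gene St8sia2 read 7.42 ± 1.15 and 13.4 ± 0.442 CPM (SD, n = 4). Ddias, an apoptosis suppressor gene, was higher by 0.96 on the log2 scale. In the other direction were Metrn, Atp5k, Hbb-bt, Ifit3b, Mien1, Igkv1-117, Srp54a, Isg15, Foxe1 and Pet100, from -1.86 to -1.17. Of these Igkv1-117 (0.0583), Foxe1 (0.119) and Pet100 (0.104) lost their calls without 94 dB replicates 3 and 4, in ranges from 3.86e-06 for Igkv1-117 to 0.119 for Foxe1. In that same fit Atp5k (0.227), Isg15 (0.185) and Ifit3b (0.270) lost theirs as well. Metrn and Mien1 overlap other genes, and Igkv1-117, Ifit3b and Srp54a have close copies, so their values are uncertain. Isg15 and Ifit3b are interferon-stimulated genes and had adjusted p of 0.0169 and 0.0366. Atp5k, Isg15 and Ifit3b lost their calls without a library: Atp5k without 94 dB replicates 3 (0.0657) or 4 (0.0633) and 105 dB replicate 3 (0.0537), in a range of 6.55e-04 to 0.227, Isg15 without 94 dB replicate 3 (0.0526), in a range of 4.31e-04 to 0.185. Ifit3b lost it without 94 dB replicates 2 (0.0742), 3 (0.0827) or 4 (0.0990) and 105 dB replicates 1 (0.0723), 2 (0.0769), 3 (0.0830) or 4 (0.0955), in a range of 0.00478 to 0.270.

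By list, mitochondrially encoded genes had 10 of 13 higher at 105 dB and none lower (11 higher adjusted over the list alone; median 0.73; camera adjusted p = 8.08e-13; adjusted p = 0.243 with an estimated correlation). Besides mt-Nd6 and mt-Nd4l, several members lost their calls without 94 dB replicates 3 and 4. By edgeR their adjusted p were 0.338 for mt-Nd5, 0.224 for mt-Atp6, 0.139 for mt-Co1 and 0.0548 for mt-Nd2. Leaving out 94 dB replicate 3 alone ended the calls of mt-Nd5 (0.0900) and mt-Atp6 (0.0557), as did replicate 4 alone (0.0873 and 0.0543). The call of mt-Nd5 also ended without 105 dB replicates 1 (0.0655) or 4 (0.0673). Removing the GC and length trend ended those of mt-Nd5 (0.181) and mt-Co1 (0.0786). Nuclear genes of oxidative phosphorylation had 11 of 38 lower and none higher (13 lower adjusted over the list alone; median -0.23; adjusted p = 3.52e-05; adjusted p = 0.969 with an estimated correlation). Immediate early genes had 2 of 45 higher and 3 lower (adjusted p = 0.908), and glucocorticoid targets 1 of 20 higher and 2 lower (adjusted p = 0.998). Heat shock genes had 2 higher and 4 lower (adjusted p = 0.575), endoplasmic reticulum stress genes 4 lower (adjusted p = 0.531) and proteasome genes 6 higher and 2 lower (adjusted p = 0.761). Erythroid genes had 4 of 14 higher and 1 lower (median 0.24; adjusted p = 0.0165; adjusted p = 0.969 with an estimated correlation), a call lost without 94 dB replicate 1 (0.146), in a range of 2.53e-05 to 0.969. Proliferation genes had 5 of 15 higher, among them Mki67 at 0.73 (adjusted p = 0.0165; adjusted p = 0.969 with an estimated correlation), lost without 94 dB replicate 1 (0.146) or 105 dB replicate 2 (0.0843), in a range of 8.15e-04 to 0.969.

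Genes called at both levels were compared next, with the 4 control libraries common to both. In the same direction 235 genes were called at 94 dB and at 105 dB, 168 higher and 67 lower, and 2 were called in opposite directions. Among the 168 were Fos, Fosb, Nr4a1, Nr4a3, Atf3, Ddit4, Per1, Sik1, Dusp1 and Nfkbia, and among the 67 were Snai2, Cx3cr1, Pou3f2 and Folh1. They were 74.4% of the 316 genes called at 105 dB. For unchanged groups set against the same controls, 20 simulations gave a mean of 0.05 shared calls and at most 1, and independent lists of these sizes would share 30.2 higher and 12.03 lower. Unchanged groups yield few calls of any kind. The simulated count therefore does not show how many calls 2 changed groups would share through their controls. With the controls split 2 and 2, the 6 arrangements gave 72 to 171 shared calls. Each level was then tested against only 2 controls, which by itself can lower the shared count and the correlations. The shared count was 109 without 105 dB replicate 2, 122 without 70 dB replicate 4 and 153 without 105 dB replicate 3. Over 19497 genes the log2 fold changes had a Pearson r of 0.612 and a Spearman rho of 0.517, beside 0.490 and 0.452 in the simulations and 0.266 to 0.385 and 0.199 to 0.375 with split controls. Their covariance was 0.0946, against 0.0269 simulated, a difference of 0.0677, and 0.0512 to 0.0657 with split controls. Of the genes called at both levels, 28 also differed between 105 and 94 dB.

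**Figure D4:**
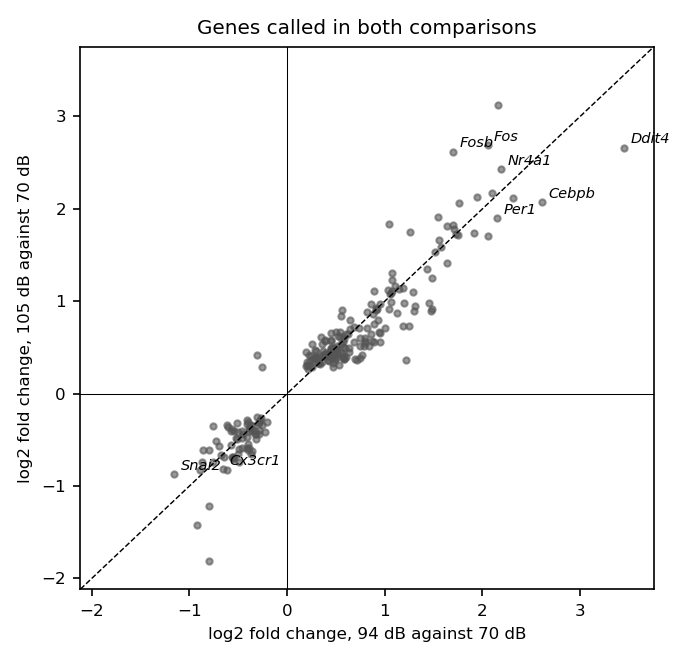
Log2 fold change at 105 dB against that at 94 dB, both relative to 70 dB, for each gene called in both comparisons; 1 point is 1 gene, and the dashed line marks equal change. Most points lie in the upper right and lower left corners (168 and 67 genes), and 2 lie in opposite directions.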

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

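The tests of fewer mitochondria and of blood or marrow cells, the look at clock genes beyond the 12, the removal of the GC and length trend and the fit without 94 dB replicates 3 and 4 were chosen after the result was seen.

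More genes passed at 94 dB than at the louder 105 dB, 5085 against 316, a ratio of 16.1, which was 36.4 without 105 dB replicate 2, 28.9 without 105 dB replicate 3, 25.6 without 70 dB replicate 4, 24.5 without 70 dB replicate 1, 38.9 with 1 surrogate variable, 10.6 with a replicate block and 6.48 with DESeq2. With the trend on GC content and length removed the ratio was 9.23, without genes over 1% of a library 16.1, and without 94 dB replicates 3 and 4 it was 4.72, so none of these accounts for the whole excess. At an unadjusted p under 0.05 by edgeR's quasi-likelihood test the counts lay closer, at 7465 and 3653. Likewise 4945 and 2107 genes had groups that did not overlap. Because the adjusted threshold is less strict where more genes change, the ratio of 16.1 does not measure how much wider the 94 dB response was. Of the 35 splits of the 8 libraries at 94 and 70 dB, the highest other than the real one gave 0 genes against 5085, at 105 and 70 dB 14 against 316, and at 105 and 94 dB 2 against 3372. The real split thus ranked as 1 of 35 in each contrast. That is the best rank 35 splits can give, and it was not adjusted over the contrasts. A split that mixes the groups puts the real effect into the spread within them, which lowers its count. A library or dissection batch that coincides with the 94 dB group was not tested, because the labels give none, and a response that is larger at 94 dB stays open as a hypothesis beside it.

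Mitochondrially encoded genes were lower at 94 dB, with a median log2 fold change of -0.81 (adjusted p = 0.116 with an estimated correlation, which ends the list's call). Removal of the GC and length trend left a median of -0.74, with 9 of the 13 genes still called, which argues against that trend as the whole cause. Fewer mitochondria, or fewer cells rich in them, was taken to lower the nuclear genes of oxidative phosphorylation too. These had a median of 0.39 instead (0.21 with the trend removed, 16 called higher). The camera call of that nuclear list also ended with an estimated correlation (adjusted p = 0.516). Nuclear transcripts need not follow the number of mitochondria in a cell, so fewer mitochondria are not excluded. A change in mitochondrial transcription or RNA turnover at 94 dB is a candidate explanation that was not tested, as is a difference in RNA handling between the groups. At 105 dB the genes did not pass, and the difference between 105 and 94 dB was itself called (median 0.73; adjusted p = 0.243 with an estimated correlation, which ends that call).

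Immediate early and glucocorticoid genes were higher at both levels, the glucocorticoid list at 94 dB with an adjusted p of 0.0608 under an estimated correlation, which ends that call. Of 12 clock genes, read as a test of the time of day of dissection, 1 was called at 105 dB (Nr1d1 at -0.66; median size of change 0.15), which is under the bound of 3 set beforehand, and 6 at 94 dB, but of 7 further clock genes 2 were called at 105 dB, Ciart at 0.97 and Per1, itself an immediate early gene, at 1.90, so a set that left these out does not exclude time of day. Blood or marrow cells would raise their own markers, yet the median of 61 such genes was 0.16 at 105 dB and 0.10 at 94 dB, beside 0.64 and 0.74 for the 45 immediate early genes. A response to the noise, or to the handling and stress that came with it, is consistent with these values as a hypothesis, the design does not part the 2, and time of day stays open beside them. For genes called at both levels, 1 of 100 regroupings of the 12 libraries, the real one, gave 235, and the highest other gave 0. A regrouping that mixes the groups puts the real effect into the spread within them, which lowers its count. Such regroupings also leave untested an overlap that comes from the common controls, for which split controls gave 72 to 171 shared calls. The split fits had fewer controls per level, so the drop from 235 is not all due to shared controls.

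Among 372 groups of 4 libraries tested for a value far from the other 3, 22 were found, where 18.6 are expected, since chance flags about 1 in 20 groups. Of the 11 at 70 dB, 6 were in replicate 1: mt-Nd6 at 1335 CPM (others 1842 to 1917), mt-Nd2 at 4187 (5550 to 5827), Plagl1 at 16.2 (21.5 to 22.3), Lamp2 at 246 (280 to 286), Foxe1 at 3.96 (1.39 to 1.54) and Tnf at 3.02 (2.49 to 2.54). Replicate 2 at 70 dB was high for Fosb at 1.96 CPM (0.98 to 1.03) and Pcna at 248 (206 to 211). Replicate 3 was low for Hbb-bt at 47.5 (57.8 to 59.3), and replicate 4 high for Necab1 at 24.9 (4.46 to 5.89) and Tvp23a at 7.22 (4.15 to 4.43). At 94 dB, replicate 1 was high for Snai2 at 6.89 CPM (5.10 to 5.17) and Dnajb1 at 154 (123 to 127), and replicate 3 low for Hk2 at 35.8 (57.9 to 59.4). At 105 dB, replicate 1 was high for Chl1 at 5.66 CPM (4.57 to 4.74), replicate 2 low for Scn9a at 4.70 (9.98 to 10.98) and high for St8sia2 at 14.1 (13.1 to 13.2) and Pcna at 280.4 (248 to 252). Replicate 3 there was low for Nr4a3 at 20.2 CPM (27.8 to 29.0) and high for Tnf at 2.54 (1.13 to 1.22), and replicate 4 low for Hbb-bt at 52.0 (86.0 to 92.6) and Relb at 14.0 (16.4 to 16.7).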

How the results depend on the processing

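The GC and length trend, the fit without 94 dB replicates 3 and 4 and the trend together with the block were chosen after the result was seen; the other settings were planned. Immediate early genes kept their calls against 70 dB in every setting run, with adjusted p up to 0.0127 at 94 dB and 6.81e-04 at 105 dB. Counts of genes past the threshold (94 to 70, 105 to 70 and 105 to 94 dB) were 5089, 315 and 3362 with DESeq2's factors, 5176, 324 and 3369 with upper-quartile factors and 5077, 316 and 3369 without genes over 1% of a library. They were 807, 71 and 142 with a fold threshold of 1.2, which asks for more than a difference from 0. At 105 against 70 dB the count was 523 with no low-count filter, 101 with 1 surrogate variable and 887 with DESeq2. With the GC and length trend removed it was 3203 at 94 dB (2281 of them among the 5085) and 1915 at 105 against 94 dB; without 94 dB replicates 3 and 4, with fewer samples, it was 1610 and 217. With libraries left out in turn the counts ran from 3452 to 5409, 126 to 399 and 1650 to 3798, and shared calls from 109 to 292. With split controls 133, 88, 72, 77 and 76 shared calls were found, and 171 in the sixth arrangement.

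The replicate numbers gave no clear pairing of the libraries: 3 of 12 same-number pairs had a correlation over 0.1, and 5 of 12 libraries correlated best with their own number. By the code in the titles 4 of 10 pairs were over 0.1, up to 0.182. The highest among pairs of unlike code was 0.147, for 70 dB replicate 3 with 105 dB replicate 1. A pairing by that number therefore stays open. With a replicate block the counts were 5084, 479 and 3366, with a block by the code number 1414 at 105 against 94 dB, and with the replicate block and the trend removed 652 at 105 against 70 dB, 2040 at 105 against 94 dB and 379 shared calls.

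Adjusted p of the heat shock list at 94 dB was 0.810 with an estimated correlation, 0.193 with fry, 0.0533 with the 8 libraries compared and 0.299 with 1 surrogate variable, and of the proteasome list 0.810, 0.139 and, without 94 dB replicates 3 and 4, 0.145. At 105 dB both lists had 0.443 with an estimated correlation, and 0.101 and 0.0893 with fry. Endoplasmic reticulum stress passed at 94 dB with DESeq2's factors (0.0498), no low-count filter (0.00375), the replicate block (0.0263), the trend removed (0.0189), both (0.0107) and without 94 dB replicates 3 and 4 (0.0361), and at 105 dB with no filter (0.0272). With libraries left out, heat shock ran from 1.34e-05 to 0.306 at 94 dB, 3.44e-16 to 4.76e-04 at 105 dB and 0.278 to 0.746 between them. Endoplasmic reticulum stress ran from 6.90e-05 to 0.306, 2.68e-04 to 0.680 and 0.278 to 0.812, the proteasome from 0.0135 to 0.213, 2.62e-07 to 0.00199 and 0.342 to 0.910, and immediate early genes from 1.78e-55 to 2.89e-38, 2.02e-115 to 3.43e-78 and 0.734 to 0.967. Between 105 and 94 dB the immediate early list was 0.123 with the trend removed, 0.949 without 94 dB replicates 3 and 4 and 0.123 with block and trend, its direction turning with each. The log2 fold change of Gclm at 94 dB changed sign, to 0.19 with block and trend. The cause was not tested for these. In the simulations, with 50 genes changed at each of 4 folds, most 1.3-fold changes went uncalled. The adjusted threshold is less strict where more genes change. At 94 against 70 dB the median size of a called change was 0.389 on the log2 scale.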

Other observations

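The tests with the GC and length trend removed, alone or with the replicate block, and without 94 dB replicates 3 and 4 were chosen after the result was seen, as were the genes named; the other tests in this part were planned.

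C1qa, C1qb and C1qc, the chains of complement C1q made by macrophages, were higher than at 70 dB by 0.88, 0.54 and 0.59 on the log2 scale, and lower at 105 than at 94 dB (-0.83, -0.37 and -0.42), while Cx3cr1 fell at both levels (-0.66 and -0.82). The macrophage list had 5 of 15 higher and 1 lower at 94 dB (camera adjusted p = 0.137), 1 lower at 105 dB (0.940) and 3 lower between them (0.0934). At 94 dB that list passed without 70 dB replicate 2 (0.0498), 94 dB replicate 1 (0.0489) or 3 (0.0470) and with no low-count filter (0.0323), in a range of 0.0323 to 0.810. Between the levels it passed without 94 dB replicate 1 (0.0373) or 3 (0.0223) and with no low-count filter (0.0332), in a range of 0.0223 to 0.969. Supporting cell genes went both ways at 94 dB, with Fbxo2 and Lfng at 0.77 and 0.71 and Tecta and Gjb2 at -0.49 and -0.41; their list had an adjusted p of 0.718 at 105 dB and 0.908 between the levels.

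The lists not yet described did not pass, except under the settings given here. In the order 94 to 70 dB, 105 to 70 dB and 105 to 94 dB, camera adjusted p were 0.233, 0.940 and 0.308 for autophagy and lysosome (8 of 29 higher and 2 lower at 94 dB, Atg16l1 at 0.27, lost without 94 dB replicates 3 and 4 at 0.0813). With fry, which tests the list against no change, it had 0.0313 at 94 dB. They were 0.241, 0.706 and 0.554 for hypoxia and glycolysis, with 4 of 18 higher and 2 lower at 94 dB and Slc2a1 at 0.36, and fry gave 0.00712 at 94 dB. Extracellular matrix had 0.924, 0.718 and 0.739, with 5 of 24 higher and 3 lower at 94 dB. Between the levels it passed with the GC and length trend removed (0.0151) and with the replicate block as well (0.0116), in a range of 0.0116 to 0.974. At 94 dB the NRF2 list had 0.148, with 6 of 22 higher, Txn1 at 0.55 and Ftl1 at 0.61, and 2 lower, and between the levels 0.888. At 94 dB it passed with fry (0.00471) and with no low-count filter (0.0323), in a range of 0.00471 to 0.516.

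Cell type lists gave 0.190, 0.305 and 0.739 for stria vascularis, 0.849, 0.331 and 0.908 for fibrocytes, 0.975, 0.431 and 0.761 for bone, and 0.991, 0.331 and 0.688 for cartilage. B cells had 0.924, 0.294 and 0.761, endothelial cells 0.975, 0.940 and 0.908, and adipocytes 0.991, 0.860 and 0.908. B cells passed at 105 dB without 70 dB replicate 3 (0.0482), in a range of 0.0482 to 0.971. Hair cell genes, which make up a small part of the tissue, had 0.940 at 105 dB and 0.761 between the levels. At 94 dB the lists of spiral ganglion neurons, central glia, erythroid cells, skeletal muscle and proliferating cells had 0.139, 0.924, 0.924, 0.975 and 0.614. Spiral ganglion neurons passed there without 70 dB replicate 2 (0.0220) or 94 dB replicate 3 (0.0424), in a range of 0.0220 to 0.810. Between 105 and 94 dB the values were 0.739 for spiral ganglion neurons, 0.761 for Schwann cells, 0.531 for central glia, 0.765 for neutrophils and 0.0934 for skeletal muscle. The muscle list passed without 94 dB replicates 1 (0.00464) or 4 (0.00423) and 105 dB replicate 4 (0.0230) and with the trend removed (0.0151; 0.0158 with the block as well), in a range of 0.00423 to 0.969. Among pathways they were 0.908 for chaperonin, 0.301 for NF-kB, 0.0883 for ribosomal proteins and 0.908 for synapse genes. The ribosomal list passed without 94 dB replicates 1 (6.52e-04) or 2 (0.00523) and 105 dB replicates 2 (0.0478) or 3 (0.00126) and with no low-count filter (0.0172), in a range of 6.52e-04 to 0.969.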
